A study of Homo sapiens with 4 samples.

How the data were processed

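The data came from 4 libraries of HEK293T cells, 1 per group: the enzyme alone or the enzyme fused to RBFOX2, each read by direct RNA and by direct cDNA nanopore sequencing, per the labels. Groups were taken from the sample titles. The labels' treatment protocol names several doxycycline doses and times without saying which applies to these libraries. Alignment used minimap2 and intervals were handled with bedtools, per the submitters' processing notes, which give no versions and name the genome build hg19. How edited reads were called is not given in the sources used here.

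Each deposited position carried the number of edited reads and of all reads, and a score. The score values that the authors deposited equal the probability that the edit fraction exceeds 0.05 under a beta distribution of edited and other reads, as recomputed here from the deposited read numbers. The read numbers are whole, never scaled, and were used in all tests, while the score was used only to grade lists. The highest coverage was 8026 and 8312 reads in direct RNA and 8139 and 8919 in direct cDNA (control, then RBFOX2), which looks like the depth limit of a pileup and caps abundant transcripts. Direct RNA files listed 4286973 positions for the control and 7538695 for RBFOX2 on hg19. Direct cDNA files aligned to transcripts listed 9396445 and 10472973 cytosines over 26688 and 25715 transcripts. Direct cDNA lists on hg19 held 848624 and 535489 positions, with a score of 0.5 or more and 0 positions in common, so they were used only to ask how direct RNA behaved at those positions. Edited reads made up 4.11% and 3.90% of reads in direct RNA and 2.20% and 2.03% in direct cDNA on transcripts.

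Transcripts were matched by identifier and version to GENCODE release 29 (GRCh38), which held 94.9% and 94.8% of those listed, and the base at every listed position of a matched transcript was a C. The 1368 and 1336 transcripts without a match were left out; their 261717 shared cytosines stood at 2.06% in the control and 1.84% with RBFOX2. Duplicated entries of the RBFOX2 library (288) lay in 1 transcript, which was left out of both libraries. Cytosines listed in several isoforms were collapsed to 1 genome position, which left 7593899 cytosines, 1678695 of them from several isoforms.

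Direct RNA positions were on hg19, for which no annotation was used here. They include cytosines and guanines of the transcript strand, and they were placed on GENCODE transcripts by the spacing of listed positions in windows of 64 bases, with at least 16 positions per window and 3 windows per offset between builds. Of 7579635 positions, 71.6% were placed on 1 gene and position, 2633452 as C, 2790277 as G and 0 as A or T, in 7525 genes. Exons written backwards matched in 1021 windows, against 3659940 for the true exons. This placement was chosen after the data were seen, and the design fixed before the data were examined had direct RNA genes untested without an annotation of the same build. All direct RNA values for genes, regions, lists, preceding bases and motifs rest on it. Positions with no strand (8950 and 19080) were left out.

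A position was tested if it had at least 10 reads in both libraries of a protocol. Positions with an edit fraction of 0.8 or more in both libraries were left out as possible genomic variants. Edited and unedited reads were compared with Fisher's exact test (two-sided) and Benjamini-Hochberg adjustment, with a threshold of 0.05. Genes and transcripts needed 3 cytosines and 100 reads in each library, and reads were pooled over their cytosines. Edit fractions are edited reads over all reads, in percent, with Clopper-Pearson 95% intervals. Log2 ratios are RBFOX2 over control with 0.5 added to edited and 1 to all reads, and ± gives the half-width of the 95% interval. For 0 edited reads the upper limit is 3 reads over the coverage. Pairs of isoforms were compared by a z test on the difference of log odds ratios, with 0.5 added to each cell. Motif tests compared called cytosines with uncalled ones of the same genes, within 100 nt on the transcript. Values relative to the overall shift multiply the odds of editing in the control so that both libraries have the same edit fraction over all shared positions.

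Gene lists were fixed before the data were examined, as were the tests above: transcripts encoded in mitochondria, transcripts known as RBFOX2-regulated, splicing factors, glycolysis, translation factors, cytoskeleton, chaperones, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, nuclear-retained RNAs, and markers of cell types that a kidney line should not hold. The percentile of a list's median log2 ratio was taken among 10000 random lists of the same size matched on coverage (seed 1). Genes were named by a rule also fixed before the data were examined. It names the 15 higher and 10 lower genes called in both protocols with the largest smaller absolute log2 ratio, and the 5 higher and 5 lower genes, transcripts and positions of each protocol with the largest difference in percentage points. It also names the 8 isoform pairs with the smallest adjusted p, 1 per gene. Up to 4 members per list with the most reads were to be named, and members named beyond those were chosen after their values were seen. Some items that the rule names are not reported here. Genes with the most higher cytosines and cytosines called in both protocols were also chosen after their values were seen.

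Alternatives fixed in advance were minimum reads of 5, 20 and 50, possible variants kept or left out from 0.5, each library over its own positions, the overall scaling, a threshold of 0.01, cytosines as units in a sign-flip test (100000 flips, at least 6 cytosines), 1000 reads per gene and 500 per transcript, windows of 50 and 200 nt, and TGCATG. Chosen after the data were seen were the restriction to cytosines after A or after C and G, cytosines as strata in a Cochran-Mantel-Haenszel test, the comparison of cytosines shared by the protocols, and the other pentamers. The tests of cytosines, genes and isoform pairs were run on simulated data made from the real coverage with 200 changed items per size, and the motif odds ratio on 4000 simulated cytosines. Transcripts went through the same test as genes and were not simulated, nor were the comparison of protocols, the pentamers and the list percentiles. Fisher's test on single cytosines found 2.5%, 20.5% and 50.0% of those with 2, 4 and 8 times the odds in direct cDNA, and 9.0%, 42.0% and 68.0% in direct RNA, with 1 unchanged position called in each. The changed cytosines were drawn only from those with at least 100 reads in both libraries and an edited read, so these shares do not hold for all tested cytosines. The pooled gene test found 82.5% of direct cDNA genes and 72.0% of direct RNA genes with 1.5 times the odds, and called 181 and 35 unchanged genes. The strata test, added for that reason, called 29 and 21. The pooled test relative to the shift called 455 and 356 unchanged genes with the shift estimated from the simulated data, and 214 and 16 with the shift known. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.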

Results

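RNA editing was measured by nanopore long-read sequencing in 4 HEK293T libraries, with 1 library per group. HEK293T is a transformed human embryonic kidney line. Control cells expressed an APOBEC cytidine deaminase alone, an enzyme that turns C into U in RNA and leaves a C-to-T change in the reads. The other cells expressed the enzyme fused to RBFOX2, an RNA-binding splicing regulator whose known motif is GCATG in DNA letters, so that edits mark RNA near the bound protein. Each construct was sequenced with 2 protocols, direct RNA and direct cDNA. How much of each construct the cells made was not measured here. Reads summed over the listed positions, with a read counted at each position that it covered, came to 259958229 in the control and 572611567 in the RBFOX2 direct RNA library. In direct cDNA aligned to transcripts they came to 862855854 and 1353214619. The median listed position held 20 and 23 reads in direct RNA and 21 and 28 reads in direct cDNA. With 1 library per group no difference below has a replicate check, and every test on reads compares 2 libraries, not 2 conditions. The intervals are 95% intervals for counting error alone, and reads over neighbouring positions are not independent molecules.

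The first comparison asked whether the fusion changed the editing level and at which kind of cytosine. In direct cDNA, cytosines that followed an A, the base that APOBEC enzymes of this kind favour together with U, were higher in the RBFOX2 library, at 1.94% of reads against 1.83% in the control (log2 ratio 0.09 ± 0.002). Cytosines that followed a U, the other favoured base, were lower with the fusion, at 1.37% against 1.45% (-0.08 ± 0.0022). Cytosines that followed a C were lower too, from 2.86% to 2.44% (-0.23 ± 0.0014), and those that followed a G went from 2.21% to 1.99% (-0.15 ± 0.0017). Cytosines in 3′ UTRs that followed an A showed the widest gap among the annotated regions, 1.94% in the control and 2.51% with the fusion (0.37 ± 0.0032). Coding cytosines that followed an A were lower with the fusion, at 1.58% against 1.76%. Over all 5370456 shared cytosines the level was 2.15% in the control and 1.97% in the RBFOX2 library, a difference of -0.178 percentage points and an overall shift of -0.13 on the log2 scale.

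In direct RNA, where all levels were higher, cytosines of 3′ UTRs that followed an A stood at 5.40% in the control and 7.03% with the fusion (log2 ratio 0.38 ± 0.0055), and coding cytosines that followed an A at 5.35% and 4.98%. All cytosines that followed an A were at 5.37% and 5.53% (0.04 ± 0.003), while those after C, G and U were lower with the fusion. Guanines were listed as well, and what was counted as an edited read there is not given in the sources used here. They stood at 2.91% in the control and 2.73% in the RBFOX2 library (-0.09). Over all 4062321 shared positions the level was 4.06% and 3.83%, a difference of -0.228 percentage points (-0.08 ± 0.0011).

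At single cytosines of direct cDNA large gains lay in MSRB2, a methionine sulfoxide reductase, and CUL4B, a scaffold of ubiquitin ligases. The MSRB2 cytosine (chromosome 10, position 23121121, GRCh38, 3′ UTR) was edited in 3 of 28 control reads and 85 of 129 RBFOX2 reads, or 10.7% (2.27 to 28.2) and 65.9% (57.0 to 74.0). The CUL4B cytosine (chromosome X, position 120526368, 3′ UTR, 2 nt from a GCATG) was edited in 0 of 66 control reads, which allows up to 4.55%, and in 55 of 105 RBFOX2 reads, or 52.4% (42.4 to 62.2). The 3 larger gains rested on fewer reads: OAZ2 (position 64691738 of chromosome 15, noncoding isoform) went from 2 of 24 to 11 of 15 reads, RASGRP3 (33482133 of chromosome 2, noncoding isoform) from 1 of 14 to 46 of 65, and SEPT7 (35831428 of chromosome 7, coding) from 2 of 28 to 10 of 15. These followed a U, a G and a C. Among the largest losses were 2 cytosines of the FSD2 3′ UTR (chromosome 15, positions 82756791 and 82756786), edited in 74 of 80 and 10 of 12 control reads and in 0 of 17 and 0 of 16 RBFOX2 reads, which allows up to 17.6% and 18.8%. AC040162.1 (67934951 of chromosome 16), ANAPC5 (121327235 of chromosome 12) and RNF181 (85597442 of chromosome 2) fell from 86.5%, 85.7% and 84.6% to 0 of 12, 0 of 10 and 0 of 10 reads, which allows up to 25%, 30% and 30%. Of these losses only the FSD2 cytosine at 82756786 followed an A. The filter for possible variants removed a position only if it was high in both libraries, so it left these in. Whether their high control levels come from edits was not tested, nor was this tested for the high RBFOX2 levels of the largest gains. In all, 8286 of 5370456 cytosines differed by Fisher's exact test (two-sided, Benjamini-Hochberg adjusted p under 0.05), 4000 higher and 4286 lower in the RBFOX2 library. Relative to the overall shift the split was 4993 higher and 2419 lower. The higher cytosines lay in 891 genes and had a median level of 1.46% in the control and 7.03% with the fusion. In simulated data, among cytosines with at least 100 reads in both libraries, the test found 20.5% of those with 4 times the odds of editing. Smaller differences at one cytosine were mostly not detectable even there, and changes at cytosines with fewer reads were not simulated.

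At single positions of direct RNA the largest gains with a gene lay in 3′ UTRs. MYL12B, a regulatory light chain of myosin (4 nt from a GCATG), went from 11.9% of 109 reads to 64.1% of 198 reads. PDHA1, a subunit of pyruvate dehydrogenase (10 nt from a GCATG), went from 10 of 82 reads to 57 of 89. PCLAF, a PCNA-binding factor (chromosome 15, position 64657904, hg19), went from 10.3% to 59.5%, and DSTN, an actin-depolymerizing protein (chromosome 20, position 17588836, hg19), from 5.00% to 54.2%. A position of chromosome 4 (140619220, hg19) that could not be placed on a transcript went from 1 of 27 to 23 of 39 reads. Among the 5 largest losses, 3 were at guanines, and the others were in IFI30 (chromosome 19, position 18288811, hg19), from 73.3% to 7.69%, and SIRT2 (chromosome 19, position 39369615, hg19), from 83.3% to 23.7%. Of 4062321 positions, 3613 differed, 1572 higher and 2041 lower with the fusion, and relative to the overall shift 1959 were higher and 1302 lower. Among the 1717721 positions placed as transcript cytosines 2896 differed, 1422 higher and 1474 lower, or 1710 and 999 relative to the shift. Guanines gave 164 higher and 549 lower calls.

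The base before the cytosine and the region set the higher cytosines apart. In direct cDNA 76.9% of them (75.5 to 78.2) followed an A, against 20.7% of all tested cytosines, and 84.6% (83.4 to 85.7) lay in 3′ UTRs, against 39.6%. In direct RNA 73.8% (71.4 to 76.0) followed an A against 21.6%, and 76.2% (73.9 to 78.4) lay in 3′ UTRs against 39.3%. The lower cytosines of direct cDNA followed a C in 48.5% of cases and an A in 11.7%, and 66.5% of them were coding. The lower cytosines of direct RNA followed a U in 39.9% of cases and an A in 20.3%, and 72.9% were coding. Calls relative to the overall shift gave lower shares after A among the higher cytosines, 72.8% and 68.8%.

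**Figure D1:**
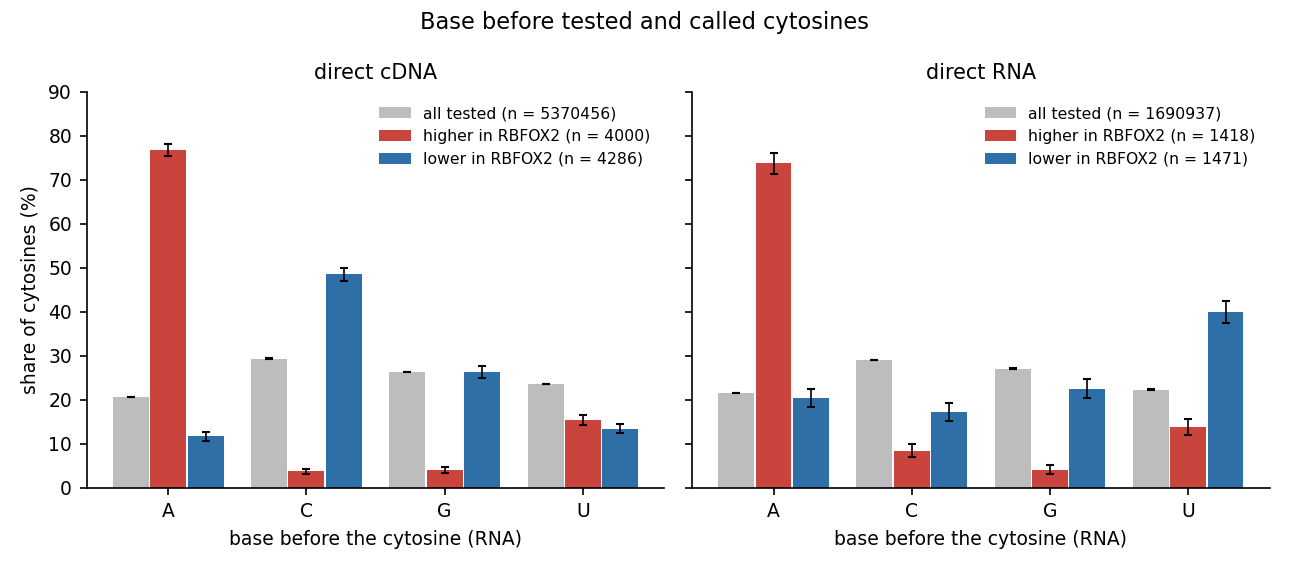
Share of cytosines (%) by the base before them, in direct cDNA and direct RNA, for all tested cytosines and for those higher or lower in the RBFOX2 library, with 95% exact binomial intervals as error bars. Among cytosines higher with the fusion, 76.9% in direct cDNA and 73.8% in direct RNA followed an A, against 20.7% and 21.6% of tested cytosines.

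The next comparison asked whether edits gained with the fusion lay near the motif of RBFOX2. Cytosines that followed an A and lay within 10 nt of GCATG were edited at 1.82% in the control and 2.55% in the RBFOX2 library of direct cDNA (log2 ratio 0.49). The ratio was lower with each step away from the motif, 0.33 at 11 to 25 nt, 0.28 at 26 to 50 nt, 0.18 at 51 to 100 nt and 0.03 beyond 500 nt or with no motif in the transcript. In direct RNA the same cytosines stood at 5.74% and 6.69% within 10 nt (0.22), and the ratio beyond 500 nt was 0.01. Cytosines after G stayed between -0.16 and -0.12 at all distances in direct cDNA. The distances pool all regions. In direct cDNA cytosines after A were at 0.37 in 3′ UTRs and -0.16 in coding sequence, so distance was not separated from region. Of the 4000 higher cytosines of direct cDNA, 33.2% had GCATG within 100 nt on the transcript strand, against 17.3% of uncalled cytosines of the same genes (odds ratio 2.38, 2.23 to 2.54, Fisher's exact p = 7.40e-130). In direct RNA the shares were 26.4% and 16.5% (odds ratio 1.83, 1.62 to 2.06, Fisher's exact p = 3.61e-21). TGCATG gave odds ratios of 3.88 and 2.78. Lower cytosines had GCATG in 15.5% and 13.0% of cases (odds ratios 0.92 and 0.83). Among all pentamers near the higher cytosines that follow an A, GCATG ranked 34 in direct cDNA (odds ratio 2.53) and 60 in direct RNA (2.05), behind AU-rich ones such as TTTTA (3.82 in direct cDNA) and TTGTA (3.35 in direct RNA). The uncalled cytosines used for the pentamers were not matched on region. Cytosines of one transcript are not replicates, so these tests describe the called sets.

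**Figure D2:**
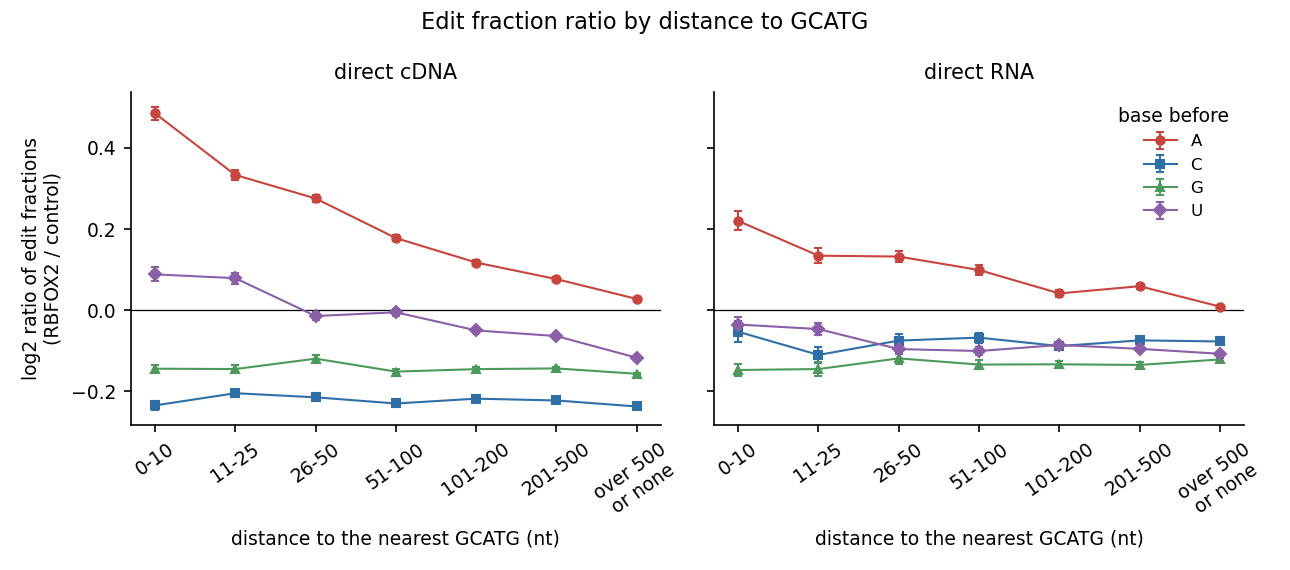
Log2 ratio of edit fractions (RBFOX2 over control) against the distance in nt to the nearest GCATG on the transcript, by the base before the cytosine, in direct cDNA and direct RNA, with 95% intervals for counting error. After A the ratio went from 0.49 within 10 nt to 0.03 beyond 500 nt in direct cDNA, and from 0.22 to 0.01 in direct RNA. All regions were pooled.

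The protocols share no library, so cytosines measured in both were compared directly. The strongest shared gain was in the 3′ UTR of PDHA1 (chromosome X, position 19359813, GRCh38, 10 nt from a GCATG), at 7.14% and 58.0% in direct cDNA and 10 of 82 and 57 of 89 reads in direct RNA, control first. HPRT1, a purine salvage enzyme (chromosome X, position 134500217, 30 nt from a GCATG), stood at 4.22% and 47.3% in direct cDNA and 5.10% and 45.5% in direct RNA. MYL12B (chromosome 18, position 3278031, 4 nt) went from 2.80% to 34.7% in direct cDNA and from 11.9% to 64.1% in direct RNA. Gains of like size lay far from a GCATG in the septin gene SEPT2 (chromosome 2, position 241353917, 1684 nt), with 38.1% in direct cDNA and 42.3% in direct RNA under the fusion, and in PARP1, a poly(ADP-ribose) polymerase (chromosome 1, position 226361210, 1662 nt), with 39.4% and 50.0%. Of 1624612 cytosines tested in both protocols, 655 were higher with the fusion in both, where 3.20 would be shared by independent lists, and 134 were lower in both, where 3.25 would be. Opposite calls numbered 35 and 49, where 3.27 and 3.17 would be shared, so independence is a low reference for all of these counts. The 655 cytosines lay in 214 genes, 94.0% followed an A, 96.2% were in 3′ UTRs and 36.3% were within 100 nt of a GCATG. After a C or G only 3 were higher in both. The most shared cytosines were in HSP90AA1 (22), SRP9 (21), ANXA5 (16), SUMO2 (16) and CALM2 (14). The 2873 cytosines after A that were higher in direct cDNA stood at 5.48% in the control and 10.6% with the fusion in direct RNA, and 92.0% (91.0 to 93.0) of those with a difference went up there.

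**Figure D3:**
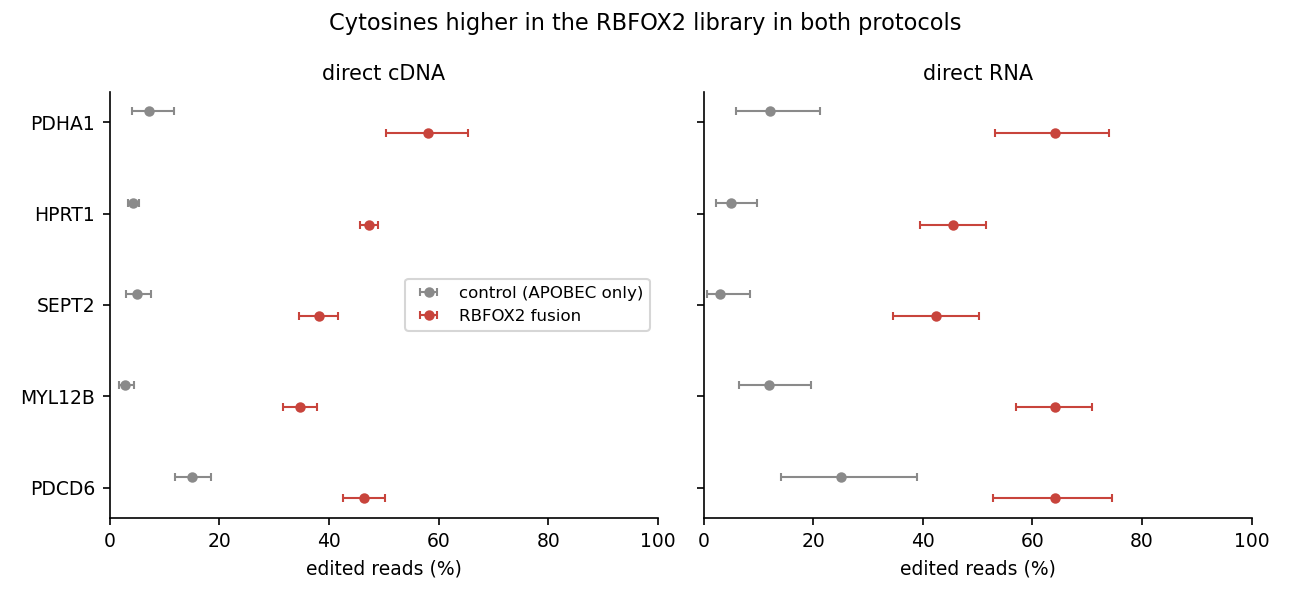
Edited reads (%) with 95% exact binomial intervals at the 5 cytosines with the largest gains called in both protocols, 1 per gene, in control (grey) and RBFOX2 (red) libraries. The PDHA1 cytosine went from 7.14% to 58.0% in direct cDNA, and the MYL12B cytosine from 11.9% to 64.1% in direct RNA.

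Reads were then pooled per gene. In direct cDNA the largest gain in percentage points was in KIDINS220, a scaffold protein of neurotrophin signalling, from 3.13% to 9.01% of reads over 39 cytosines (log2 ratio 1.49 ± 0.70, Fisher's exact test, adjusted p = 1.26e-05). FRG2B, ZNF321P, GBP4 and SERPINB9 followed, with RBFOX2 levels of 5.09%, 6.04%, 7.48% and 5.70% against 1.44%, 2.40%, 3.98% and 2.65%. These rested on few reads, and FRG2B and the pseudogene ZNF321P share sequence with relatives. The largest losses were in PLCXD2 (8.94% to 2.77%), NEO1, a netrin receptor (6.56% to 1.19%, from 8 and 2 edited reads, log2 ratio -2.22 ± 2.01), WDR37 (4.52% to 0 of 257 reads, which allows up to 1.17%), the pseudogene RPS4XP5 (17.8% to 14.1%, uncertain because its parent gene is nearly identical) and NPB, a neuropeptide precursor (4.16% to 0.601%). NEO1 and RPS4XP5 were not called relative to the overall shift. Of 10974 genes tested, 4845 differed, 639 higher and 4206 lower with the fusion. Relative to the overall shift of -0.13 the calls were 1498 higher and 1608 lower, and 41 genes called lower became higher. Counting the cytosines that follow an A alone, 1258 genes were higher and 818 lower. In simulated data with unchanged genes the pooled test called 181 of them, and a test with cytosines as strata called 29; on the real libraries that test called 505 higher and 4678 lower. A sign-flip test with cytosines as units called 271 higher and 3851 lower, and kept 228 of the 639 higher genes.

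In direct RNA the largest gains were in USP46, a deubiquitinase (2.34% to 14.0%, log2 ratio 2.47 ± 1.26, Fisher's exact test, adjusted p = 3.55e-05), PPIC, a cyclophilin (4.53% to 12.5%), HK2, a hexokinase (3.33% to 10.4%), and TAF13, a subunit of the general transcription factor TFIID (3.17% to 9.72%). The largest losses were in ST6GALNAC4, a sialyltransferase (6.20% to 2.09%), MAN1A2, a mannosidase (7.49% to 3.38%), LRP5, a Wnt co-receptor (8.11% to 4.14%), MED25, a Mediator subunit (10.5% to 6.89%), and RPL41P2 (8.76% to 5.19%), a pseudogene that is uncertain because its copies are nearly identical. All of these genes kept their call relative to the overall shift. In direct cDNA PPIC was also higher, and ST6GALNAC4, MAN1A2 and LRP5 were also lower. USP46, HK2, TAF13, MED25 and RPL41P2 were not called there, although relative to the shift TAF13 and RPL41P2 were higher. HK2 went the other way in direct cDNA, at 1.46% and 1.12%, and was called lower with cytosines as strata. Of 6049 genes, 1634 differed, 515 higher and 1119 lower, and relative to the shift 937 were higher and 616 lower. After A alone 721 genes were higher and 250 lower.

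Genes called alike in both protocols came next. Large gains were found in ATP13A3, an endosomal transporter, at 1.68% and 4.30% in direct cDNA and 3.78% and 6.43% in direct RNA, control first (log2 ratios 1.32 and 0.76). Others were in KIDINS220 (1.49 and 0.71), LRBA, a regulator of vesicle trafficking (0.63 and 0.86), and PTPN11, the phosphatase SHP2 (0.58 and 0.77). CALM2, which encodes calmodulin, held 35 higher cytosines in direct cDNA and 14 in direct RNA and had ratios of 0.55 and 0.57. ABHD3, DYNLT3, MZT1, HIGD1A, MAPK6, B2M, C1D, ATF7IP2 and LAPTM4A followed, with ratios of at least 0.46 in both protocols, among them B2M, the light chain of HLA class I, at 1.17 in direct cDNA and 0.49 in direct RNA, where it went from 6.13% to 8.63%. The lower genes were led by LARS2, the mitochondrial leucyl-tRNA synthetase (-0.58 and -0.53), and MED15, a Mediator subunit (-0.45 and -0.43). LANCL2, RELA, a subunit of NF-kappaB (-0.42 and -0.54), LRP5, NUCB1, PLXNB2, MVK, HMG20B and CRTC2 followed. Each of these genes kept its call relative to the overall shift in both protocols, except PLXNB2 and CRTC2 in direct RNA. Counting cytosines after A alone, the higher genes kept their calls except ATP13A3 in direct cDNA and ATF7IP2 in direct RNA. Of the lower genes only HMG20B stayed called in direct RNA, where MED15 (0.15), PLXNB2 (0.06) and CRTC2 (0.04) turned positive. The others stayed negative there without a call: LANCL2 (-0.77), RELA (-0.50), LRP5 (-0.48), LARS2 (-0.33), NUCB1 (-0.20) and MVK (-0.05). In direct cDNA LARS2 (-0.48), MED15 (-0.38), RELA (-0.36) and MVK (-0.36) lost their call but stayed negative. Cytosines after A hold fewer reads, so a lost call need not mean a lost difference.

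Of 5926 genes tested in both protocols, 163 were higher in both, where 36.2 would be shared by independent lists, and 839 were lower in both, where 581 would be. Opposite calls numbered 147, where 346 would be expected. Relative to the shift in each protocol the counts were 387 higher and 221 lower in both, with 159 opposite. Across genes the log2 ratios of the protocols had a Pearson's r of 0.19 and a Spearman's rho of 0.20. For cytosines after A alone r was 0.36, with 452 genes higher in both, and after C or G it was -0.0147, with 0 genes higher in both. Genes are not independent replicates, so no p-value was computed for these values.

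Gene lists fixed in advance differed in how they moved. Transcripts encoded in mitochondria, a compartment that a cytosolic or nuclear enzyme should not reach, fell in direct cDNA in all 13 tested members, from 2.28% to 1.77% over the list (log2 ratio -0.37 ± 0.0073, -0.24 relative to the overall shift), with MT-CO2 from 2.59% to 1.46% and MT-ND4 from 2.04% to 1.61%. In direct RNA 10 of 12 fell, from 6.24% to 6.02% (-0.05), but relative to the shift the list was at 0.0269, with 3 members higher and 2 lower. Splicing factors rose in direct RNA in 7 of 24 members, with 1 lower and 16 not called (0.06 over the list), among them HNRNPC from 4.61% to 5.43%, HNRNPA2B1 from 4.78% to 5.64% and HNRNPK from 5.28% to 5.66%. Relative to the shift 15 were higher and 0 lower. In direct cDNA 3 splicing factors rose and 15 fell (-0.09), which turned to 10 higher and 7 lower (0.04) relative to the shift. Counting cytosines after A alone, 17 of 23 rose in direct RNA and 10 of 24 in direct cDNA. Transcripts known as RBFOX2-regulated rose in direct RNA in 3 of 7 members, APP from 5.49% to 6.08%, ECT2 from 4.01% to 5.51% and ENAH from 4.98% to 5.84%, and 0 fell. In direct cDNA 0 rose and 1, APP, fell, from 2.30% to 2.03%, a call that was lost relative to the shift, where ENAH alone was higher. After A alone 2 members rose in direct cDNA and 0 fell, ENAH (log2 ratio 0.24) and APP (0.32), so the direction of APP turned, and 3 rose in direct RNA. RBFOX2 itself was not called in either protocol, at 1.94% and 1.88% in direct cDNA and 2.03% and 2.66% in direct RNA.

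Cytosolic ribosomal proteins fell in direct RNA in 74 of 83 members, with 1 higher (5.61% to 4.91%, -0.19 and -0.11 relative to the shift, with 59 lower and 3 higher), among them RPL13 from 5.07% to 3.99% and RPLP0 from 5.31% to 4.75%. In direct cDNA 60 of 84 fell and 14 rose, RPS2 from 2.77% to 2.06% and RPL3 from 1.58% to 1.81%, and relative to the shift the split turned to 29 lower and 33 higher. These genes have many near-identical pseudogenes, so their values are uncertain, as are those of GAPDH and TUBA1B. Translation factors fell in 16 of 20 members in direct cDNA (EEF2 from 1.66% to 1.42%) with 1 higher, and in 7 in direct RNA (EEF2 from 5.15% to 4.40%) with 3 higher. These counts relative to the shift became 8 lower and 3 higher in direct cDNA, and 4 lower and 6 higher in direct RNA. Cytoskeletal genes fell in 10 of 14 in direct cDNA (TUBA1B from 2.04% to 1.61%) with 1 higher, while 3 rose and 3 fell in direct RNA, with STMN1, a microtubule destabilizer, higher in both (2.68% to 2.85% and 4.86% to 6.46%). The cytoskeleton relative to the shift had 5 lower and 3 higher in direct cDNA, and 2 lower and 7 higher in direct RNA. Chaperones fell in 15 of 18 in direct cDNA (HSPA8 from 2.07% to 1.79%) with 2 higher, and 4 rose and 4 fell in direct RNA, with HSP90AA1 higher in both (2.44% to 2.67% and 5.21% to 6.60%). Chaperones relative to the shift had 7 lower and 2 higher in direct cDNA, and 1 lower and 9 higher in direct RNA. Nuclear-encoded oxidative phosphorylation genes fell in 18 of 24 in direct cDNA and 12 of 24 in direct RNA, ATP5F1B in both (2.03% to 1.70% and 5.27% to 4.79%), with 1 and 3 higher, and relative to the shift 7 and 7 were lower and 6 and 4 higher. Glycolytic genes fell in 7 of 14 in direct cDNA, with 2 higher, and in 4 of 14 in direct RNA, with 3 higher, GAPDH falling in both (-0.19 in direct cDNA, and 5.83% to 5.04% in direct RNA). Glycolysis relative to the shift had 3 lower and 4 higher in direct cDNA, and 3 lower and 6 higher in direct RNA. The pooled ratio of splicing factors turned positive relative to the shift in direct cDNA, and that of mitochondrial transcripts and the cytoskeleton in direct RNA. Glycolysis in direct cDNA (0.00997) was positive by less than its half-width of 0.0104. So were translation factors (0.00266, half-width 0.00911) and oxidative phosphorylation (0.00211, half-width 0.0116) in direct RNA. Their unscaled ratios (-0.0770 and -0.0775) lay just below that of all transcript cytosines (-0.0755). Among 10000 random lists matched on coverage, the medians of mitochondrial transcripts lay at percentile 0 in direct cDNA and 60.2 in direct RNA, and those of ribosomal proteins at 99.2 and 0. Percentiles in direct cDNA and direct RNA were 74.9 and 99.99 for splicing factors, 78.2 and 99.3 for RBFOX2-regulated transcripts, 86.2 and 96.7 for glycolysis, and 8.37 and 81.6 for translation factors. They were 62.8 and 95.6 for the cytoskeleton, 44.5 and 99.6 for chaperones, and 86.7 and 54.8 for oxidative phosphorylation, and 61.9 for the markers of other cell types in direct cDNA. Of these markers, COL1A1 and EPCAM could be tested in direct cDNA and neither was called, and 0 were tested in direct RNA. Of the nuclear-retained RNAs 0 could be tested in either protocol. Adjusted over the list alone, the direct cDNA counts became 4 higher for splicing factors, 8 lower for glycolysis, 18 lower for translation factors, 12 lower for the cytoskeleton, 16 lower for chaperones and 62 lower for ribosomal proteins. Adjusted over the list alone in direct RNA, 8 splicing factors, 5 glycolytic genes and 5 chaperones were higher, and 1 RBFOX2-regulated gene, 5 glycolytic genes, 8 translation factors, 5 chaperones, 13 oxidative phosphorylation genes and 75 ribosomal proteins were lower. The other counts stayed as given.

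**Figure D4:**
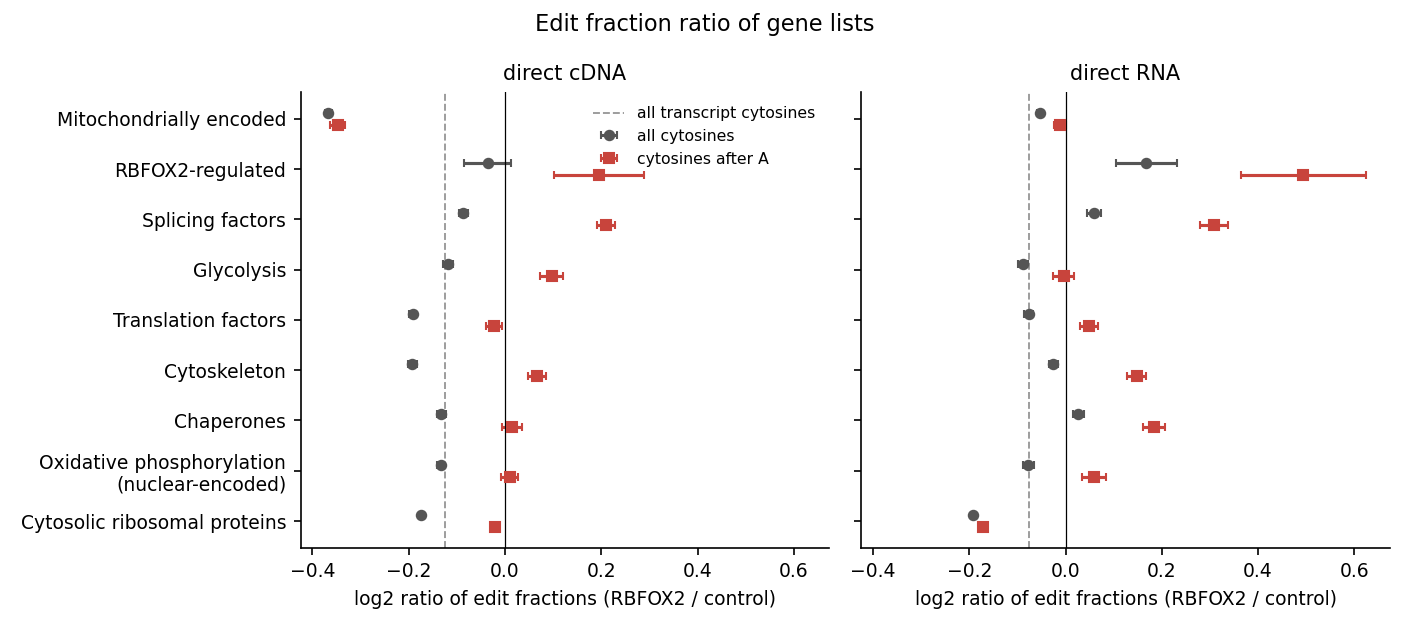
Log2 ratio of edit fractions (RBFOX2 over control) pooled over the gene lists, for all cytosines (grey) and for cytosines after A (red), with 95% intervals for counting error and a dashed line at the ratio over all transcript cytosines. Splicing factors after A stood at 0.21 in direct cDNA and 0.31 in direct RNA. Relative to the dashed line, negative all-cytosine ratios of splicing factors and glycolysis in direct cDNA, and of mitochondrial transcripts and the cytoskeleton in direct RNA, change sign. For glycolysis the line lies within the interval.

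The direct cDNA reads aligned to transcripts also allowed isoforms to be compared. Among transcripts the largest gains were in CLIP1-205, an isoform of a microtubule-binding protein (3.50% to 9.46%), a transcript of KIDINS220 (3.13% to 9.01%), LACTB-202 (1.69% to 7.25%), LPP-222 (3.41% to 8.85%) and UBE2V1-206 (0 of 184 reads, which allows up to 1.63%, to 5.22%). The largest losses were in PEX26-204 (10.2% to 3.60%), EVA1C-209 (13.0% to 6.45%), PLCXD2-205 (8.94% to 2.77%), a transcript of ZNF254 (7.78% to 2.29%) and EMG1-205 (4.85% to 0 of 198 reads, which allows up to 1.52%). Of 21060 transcripts, 6335 differed, 917 higher and 5418 lower, and relative to the shift 1959 were higher and 2131 lower.

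Pairs of isoforms that responded differently were ranked by adjusted p, which favours deeply read genes, and those named here include ribosomal protein genes, which are uncertain because of near-identical copies. RPS2-211 fell from 3.72% to 2.30% while RPS2-213 went from 3.23% to 2.90%. RPL41-202 was at 1.90% and 2.18% while RPL41-204 was at 2.95% and 2.03%. An isoform of RPL12 was at 1.45% and 0.854%, and RPL12-204 at 2.55% and 2.53%. RPS3A, RPL13, RPL4 and NACA, a subunit of the nascent polypeptide-associated complex, had pairs of the same kind, with 1 NACA isoform at 1.58% and 1.77% and the other at 2.63% and 2.03%. All of these pairs were also called when only cytosines common to both isoforms were counted. Of 4517 genes with at least 2 testable isoforms, 906 had a pair that differed (z test on the difference of log odds ratios, Benjamini-Hochberg adjusted p under 0.05). How the authors assigned reads shared by isoforms is not given in the sources used here. In simulated data with 1.5 times the odds in 1 isoform, 43.0% of the changed genes had a called pair, and 15 unchanged genes were called. The simulation drew reads from each transcript's pooled edit fraction, so it does not cover an uneven spread of reads over cytosines.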

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

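The tests of read error and of the preceding base used below were chosen only after the results were seen, while the test on listed positions was set before the data were examined.

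The protocols differed in each of the 12 quantities compared, log2 ratios of RBFOX2 over control and a log2 odds ratio. The z test used counting error (Benjamini-Hochberg adjusted), which ignores variation between cultures and library preparations. Each protocol was taken over its own tested cytosines, in all 5370456 in direct cDNA and 1717721 placed ones in direct RNA. The differences may therefore also come from the cytosines covered. Direct cDNA minus direct RNA was -0.0497 over all transcript cytosines but 0.0469 over those that follow an A. Among the gene lists mitochondrial transcripts differed most, at -0.315, where direct cDNA showed a loss in all 13 members and direct RNA a smaller one that turned positive relative to the shift (0.0269). The difference was -0.204 for RBFOX2-regulated transcripts, -0.146 for splicing factors, -0.167 for the cytoskeleton, -0.159 for chaperones, -0.115 for translation factors, -0.0556 for oxidative phosphorylation and -0.0293 for glycolysis. Ribosomal proteins differed by 0.0164. The log2 odds ratio of GCATG near higher cytosines was 0.384 larger in direct cDNA.

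Direct cDNA held 4286 cytosines that were lower with RBFOX2. A candidate explanation is a lower C-to-T read error rate in the RBFOX2 direct cDNA library. Mitochondrial transcripts, which the enzyme should not reach, had a log2 ratio of -0.367 (-0.375 to -0.360). A lower read error rate would give a ratio below 0, and only the sign was asked for. Nuclear transcripts were at -0.122, and whether the same error rate could give both values was not tested. Fewer edits by the enzyme might place the lower cytosines after A or U. In direct cDNA 11.7% (10.7 to 12.7) of them followed an A, against 20.7% of those tested, and 13.5% a U, against 23.6%. In direct RNA 39.9% of the lower cytosines followed a U, against 22.3% of those tested. A loss is easier to call where the control level is high. Control levels in direct cDNA were 2.86% after C, 2.21% after G, 1.83% after A and 1.45% after U. In direct RNA they were highest after U, at 8.98%. These shares therefore cannot decide on fewer edits in either protocol. With 1 library per group, a difference in base calling, depth or RNA quality could not be separated from the construct, and mitochondrial RNA may respond to the construct in other ways.

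Positions listed only for RBFOX2 among the direct cDNA genome lists, which no comparison above uses, had a higher log2 ratio in direct RNA (3.90% and 3.87%, -0.01) than positions listed only for the control (4.53% and 4.34%, -0.06). The difference was 0.0487 (0.0262 to 0.0711), and 0.0633 and 0.103 for positions with a score of 0.9 and 0.99 or more. Read errors of direct cDNA with no counterpart in direct RNA would give a difference of 0 only if both lists held like positions. The lists were not matched on region or gene, and direct RNA ratios were 0.073 in 3′ UTRs and -0.131 in coding sequence. The test therefore cannot decide on read errors. With cytosines as strata the RBFOX2 list was at -0.0208 and the control list at -0.0497. Of 535489 positions of the RBFOX2 list 17996 could be tested in direct RNA, with 1 higher and 1 lower. The difference is small, and most listed positions may still be background.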

How the results depend on the processing

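Restrictions by preceding base, cytosines as strata, and list values relative to the shift were tests chosen only after the results were seen. Over the alternatives run, headline values were graded as the same in 68 cases, moved in 60 and reversed in 9. Ratios and shares were graded by their margin, counts by their fold change, and motif odds ratios by whether their interval stayed above 1. The 9 include lists that turned positive by less than their half-width, and Pearson's r after C or G, as given below. No paired analysis was run, because each comparison had 1 library per group and the protocols were taken as separate measurements. Introns were not counted as a region, and 455561 positions of direct RNA, with 118 higher and 199 lower calls, were placed on no transcript.

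The overall log2 ratio of direct cDNA (-0.125) was 0.0900 for cytosines after A, a reversal that follows from the choice of cytosines, and -0.196 after C or G. It was -0.127 with 50 reads, -0.123 with possible variants kept, -0.127 with positions from 0.5 left out, -0.117 with each library over its own positions and -0.160 with cytosines as strata. That of direct RNA (-0.0833) reversed to 0.0431 after A and was -0.105 after C or G. It was -0.0858 with 20 reads, -0.0930 with 50, -0.0820 with variants kept, -0.0794 without positions from 0.5, -0.0764 over own positions, -0.0774 with strata and -0.0755 over placed cytosines. The cause was not tested for the other moves.

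Genes called in direct cDNA (4845) became 3106 relative to the shift, 2970 with strata relative to the shift, 2076 after A and 2084 after A with strata. With strata alone 5183 were called, among them 484 of the 639 higher genes and 4144 of the lower ones, with 0 opposite. With cytosines as units in the sign-flip test 4122 were called, 271 higher and 3851 lower. That test kept 228 of the 639 higher genes, left 398 uncalled and gave 13 the opposite direction, and the cause was not tested. It kept 3377 of the lower genes, with 2 opposite. In direct RNA the test called 1255 and kept 345 of 515 higher and 822 of 1119 lower genes, with 0 opposite. Genes called in direct RNA (1634) became 971 after A, 716 after C or G, 1057 after A with strata and 860 with 50 reads, where fewer genes could be tested. Over own positions 1906 were called, 856 higher and 1050 lower. Transcripts went from 6335 to 4090 relative to the shift. Genes called alike in both protocols (1002) became 608 relative to the shift, 539 after A, 555 after A with strata and 512 after C or G. Pearson's r (0.189) was 0.254 with 20 reads, 0.249 with 1000 reads per gene and 0.364 after A. After C or G it was lost, at -0.0147, which is smaller than the half-width of 0.0244 of the main value. Calls of single positions at a threshold of 0.01 were 3098 higher and 3030 lower in direct cDNA, so the majority turned there as it did relative to the shift. Over placed cytosines of direct RNA 49.1% were higher, against 43.5% of all positions. Calls numbered 6128 to 10217 in direct cDNA and 2620 to 5281 in direct RNA.

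Relative to the shift, 72.8% and 68.8% of higher cytosines followed an A, and 80.4% and 70.9% lay in 3′ UTRs. The odds ratio of GCATG or TGCATG stayed between 2.02 and 3.91 in direct cDNA and between 1.60 and 3.11 in direct RNA over the windows, motifs and sets of higher cytosines run.

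Relative to the shift, which adds a constant, the direct cDNA lists were at -0.240 for mitochondrial transcripts, 0.0917 for RBFOX2-regulated ones, -0.0644 for translation factors, -0.0645 for the cytoskeleton, -0.00461 for chaperones, -0.00535 for oxidative phosphorylation and -0.0472 for ribosomal proteins. Splicing factors (0.0413) reversed, while glycolysis (0.00997) was positive by less than its half-width of 0.0104. In direct RNA mitochondrial transcripts (0.0269) and the cytoskeleton (0.0543) reversed. Translation factors (0.00266) and oxidative phosphorylation (0.00211) were positive by less than their half-widths (0.00911 and 0.0116), so no reversal was shown for them. RBFOX2-regulated transcripts were at 0.247, splicing factors at 0.139, chaperones at 0.106, glycolysis at -0.00883 and ribosomal proteins at -0.112. With cytosines as strata direct cDNA gave -0.394 for mitochondrial transcripts, -0.128 for splicing factors, -0.146 for glycolysis, -0.244 for translation factors, -0.208 for the cytoskeleton, -0.173 for chaperones and -0.163 for oxidative phosphorylation. Direct RNA gave -0.0683 for mitochondrial transcripts, 0.233 for RBFOX2-regulated ones, 0.0834 for splicing factors, -0.0892 for translation factors, -0.00473 for the cytoskeleton, 0.0522 for chaperones and -0.187 for ribosomal proteins. For strata the cause was not tested.

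Counting a named gene in each protocol, 66 calls were kept with strata and 63 relative to the shift. PLXNB2 (-0.32) and CRTC2 (-0.34) in direct RNA and NEO1 (-2.10) and RPS4XP5 (-0.21) in direct cDNA did not. At a threshold of 0.01, 12 of 20 named positions stayed called, and those in OAZ2, RASGRP3, SEPT7, ANAPC5, IFI30, SIRT2 and 2 guanines did not. Genes with isoforms that differed numbered 1039 with 5 reads, 666 with 20, 963 with 500 reads per transcript and 737 of 837 on common cytosines. Depth limits single cytosines most. In simulated direct cDNA data 50.0% of those with 8 times the odds and at least 100 reads in both libraries were found.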

Other observations

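The tests on the preceding base and on other pentamers were chosen only after the results were seen.

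Genes with the most higher cytosines in direct cDNA were of different kinds. HPRT1 and PRDX3, a mitochondrial peroxiredoxin, held 36 each, all in 3′ UTRs, and their cytosines after A stood at 2.04% and 6.82% in HPRT1 and 2.76% and 6.57% in PRDX3, control first. SRP9, CALM2, H3F3A, CCNI, PSAT1 and AP3S1 held 32 to 35, with 25 of the 35 in CALM2 and 26 of the 32 in AP3S1 within 100 nt of GCATG, and 0 in H3F3A and PSAT1. The ribosomal protein gene RPS4X held 37, of which 11 followed an A and 2 were in the 3′ UTR, and its cytosines after A stood at 3.82% and 3.84% in direct RNA. RPL3 (5 after A, 0 in the 3′ UTR) and RPL13A (8 after A, 1 in the 3′ UTR) were of the same kind, and their cytosines after A were lower with RBFOX2 in direct RNA, at 5.78% and 4.81%, and 5.04% and 3.99%. These genes share reads with near-identical copies and are uncertain.

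The higher cytosines of direct cDNA were weighed against 4 explanations. Read errors with no editing would not be expected to favour the enzyme's preferred base before the cytosine, and 76.9% (75.5 to 78.2) followed an A. Genomic variants of the RBFOX2 line would be expected at high edit fractions, and the median was 7.03%. A median does not exclude variants at single cytosines, and 45 of the 4000 stood at 40% or more with the fusion. Binding of RBFOX2 near its motif is a candidate explanation, with an odds ratio of GCATG within 100 nt of 2.47 (2.29 to 2.67) among cytosines after A. For AU-rich sequence alone, GCATG was set against other orders of its letters. Against up to 10 uncalled cytosines per called one GCATG had 2.53, while the highest of the other orders had 1.16. Several AU-rich pentamers ranked above GCATG. The uncalled cytosines were not matched on region, while 2847 of the 3075 called ones lay in 3′ UTRs, so this comparison cannot separate AU-rich sequence from 3′ UTR sequence. Within 3′ UTRs GCATG had an odds ratio of 2.21 (2.03 to 2.39), and other pentamers were not tested there. A part played by AU-rich sequence stays open, as does the amount of each construct, which was not tested.

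Isoforms of 1 gene that differ in their response could differ only because they cover different cytosines. On common cytosines 87.4% (85.9 to 88.8) of the called pairs that could be tested were called in the same direction and 2 in the opposite one. Cytosines covered by only 1 isoform therefore do not account for most of them. Reads were still pooled over the common cytosines, so an unequal spread of reads over cytosines of different levels was not tested. How reads were divided among isoforms was not tested.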
